A study of Drosophila melanogaster with 3 samples.

How the data were processed

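ChIP-seq of CG12155-eGFP was done in 3 biological replicates of whole embryos aged 0 to 24 hours, per the labels, with chromatin sheared by sonication to fragments of 200 to 800 bp and an antibody against GFP. The ENCODE consortium made the files. Replicate numbers and the single group were taken from the labels, and the replicates are separate biological samples by those labels. The files used were 10 peak lists, 5 on dm6 and 5 on dm3: a relaxed list of peaks and background for each replicate, called on that sample alone, a relaxed list for the pooled replicates, and an optimal list of peaks that pass the irreproducible discovery rate (IDR), per the notes deposited with the files. The aligner, the peak caller, its settings and the IDR threshold are not given in the sources used here. A possible control experiment is named in the labels and was not analysed here.

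Each deposited list gives, per region, a signal value set by the authors' peak caller relative to a control. The scale of the signal is not stated and differs between lists, so signals were used only to rank regions within a list. The deposited q-value column is a −log10 value in this file format, and all optimal peaks share its highest value, 4.07 on dm6, so it was not used to rank. All 5202 optimal dm6 peaks were found among the 5202 strongest of the pooled relaxed list, and 5148 of the optimal intervals were distinct, since some intervals are listed with more than 1 summit. Several relaxed lists hold exactly 30000 regions, and list lengths were not compared between replicates. The files hold no read counts, so the depth of each library is unknown and no value could be weighted by it.

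Genes, exons and transcription start sites came from Ensembl release 115, and sequence from the RefSeq copy of the Release 6 assembly, whose arms equal those of dm6. Only 2L, 2R, 3L, 3R, 4 and X were used, with 13945 protein-coding genes and 19252 TSS positions. No dm3 reference was used, so dm3 lists gave counts, ranks and overlaps only. A promoter was the 500 bp either side of a protein-coding TSS. Summits were placed in order of priority in promoter, 5' UTR, coding exon, 3' UTR, other exon, intron or intergenic sequence.

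Support in a replicate was an overlap of 1 bp or more with its 5202 strongest regions. Chance was taken from 1000 rotations of the peaks along their own arm (permutation test, two-sided), and the smallest p this allows is 0.001. Gene lists, head-to-head genes and chromosomes were tested with Fisher's exact test, two-sided, against all other protein-coding genes or against 2L, 2R, 3L and 3R. Motifs were tested with the exact McNemar test, two-sided, between summit and flanks of the same peak. Values of p were adjusted by Benjamini-Hochberg over the 22 gene lists, over the 22 motifs, over all 6-mers, over the 7 genomic classes and over the 2 chromosome tests. Peaks and genes are not replicates: p-values describe this one peak set, and the SD over the 3 replicates, taken from the 5202 strongest peaks of each, is given beside them. For a count of 0, the limit that 3 counts would give is printed beside the Wilson bound. Intervals are 95% Wilson intervals, or from 2000 bootstrap draws over peaks for the median distance.

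Gene lists, motifs, tests, alternatives and the rule for named genes were fixed before the data were examined. Of the listed symbols, 7 matched no single gene in the annotation and were left out. The rule named the 20 strongest optimal peaks supported by all 3 replicates, CG12155, the 4 members with the strongest promoter peak of each list past adjusted p 0.05, and the 5 6-mers with the largest ratio past that threshold and at 100 or more summits. Alternatives were promoter windows of 200 and 1000 bp, stricter peak sets, peaks supported by both remaining replicates with each replicate left out, other overlaps, backgrounds and control regions, motif windows of 100 bp, flanks 200 bp away, 1 TSS per gene, and dm3. Leaving a replicate out did not remake the optimal set, which draws on the pool of all replicates. Added after the data were seen were 20 dinucleotide-shuffled copies of each summit window and of windows of the same length 500 bp to either side, with intervals from 2000 bootstrap draws over peaks, gene lists without head-to-head genes, summits under 250 bp from a stronger one left out, and the overlap of each replicate's 5202 strongest peaks with those of each other replicate.

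The procedures were tested on simulated data. With 5 gene lists given 4 times the odds of being bound in 50 simulations over 13945 genes, 84.8% of these were recovered and 0.824% of unrelated lists were called. A motif planted at 3.46% of 5202 random positions was recovered, and so was a planted 6-mer, with 0 of 22 motifs and 0% of 2080 6-mers called at random positions without planting. These positions were drawn uniformly along the arms, while optimal summits lay in a dip of GC (35.6% against 44.2% in windows centred 500 bp to either side). The rates therefore do not cover calls that base composition alone would give. With 30% of summits placed at TSSs, the rotation test called the excess (permutation test, p = 0.01, the smallest that simulation could give), and it called none of 20 random sets. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9.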

Results

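Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the protein encoded by CG12155 in whole Drosophila melanogaster embryos. The protein was tagged at its C terminus with the green fluorescent protein eGFP. Peaks mark where chromatin was enriched with an antibody against GFP. No control experiment was analysed here, so enrichment that does not depend on the tagged protein was not assessed. The labels give 1 group of 3 biological replicates, each of mixed-sex embryos aged 0 to 24 hours from a transgenic line, precipitated with an antibody against GFP. With 1 group, the design asks where the tagged protein was found and how far the replicates share these places, and it holds no comparison between conditions. On genome build dm6, replicates 1, 2 and 3 had relaxed lists of 30000, 29643 and 30000 regions, which hold peaks together with background. The pooled replicates gave 30000 relaxed regions, and the optimal set, which the authors give as passing IDR, held 5202 peaks with a median width of 430 bp. The same peaks were the 5202 strongest pooled regions, so pooled signal rank alone gives membership in the set. The files give no read counts, so depth is unknown. All intervals below cover counting error over peaks or genes only.

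The tagged gene itself lay beside a peak in all 3 replicates. CG12155 (FBgn0029957) is a gene of 2 exons on the plus strand of X:7728755-7731729 in dm6, and its start faces that of NELF-B, which encodes a subunit of the negative elongation factor. An optimal peak at X:7728301-7728544, with its summit 322 bp upstream of the CG12155 transcription start site (TSS), ranked 826 of the 5202. A second, at X:7728488-7728917, had its summit 52 bp upstream of the same TSS and ranked 1483. A stronger peak within 5 kb, at X:7734395-7734815, ranked 240 and covered the start of Pdp, the gene of a pyruvate dehydrogenase phosphatase, near that of Rab39. In the relaxed lists of replicates 1, 2 and 3, the matches of the first peak ranked 975, 525 and 1110. Those of the second ranked 1230, 1287 and 3416, and those of the third 335, 216 and 190. A tagged transgene can add copies of this locus and raise its coverage.

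**Figure D1:**
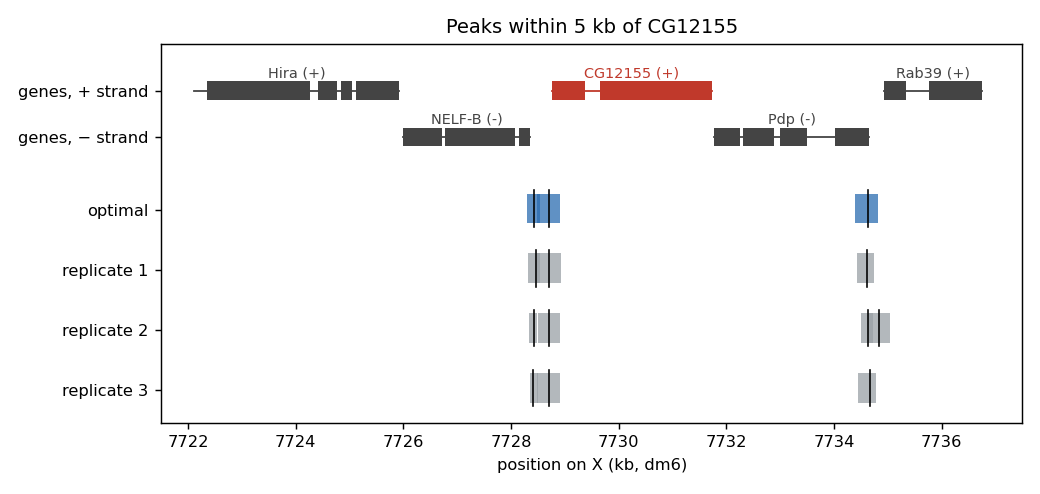
Map of the genes and peaks within 5 kb of CG12155 on X in dm6, with position in kb, exons as boxes, optimal peaks in blue, peaks among the 5202 strongest of each replicate in grey, and summits as black lines. Peaks at the shared CG12155 and NELF-B start and at the Pdp start were found in all 3 replicates.

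The strongest peaks sat mostly at the starts of genes. The highest signal in the pooled list, 9984, was at 2R:18160139-18160923 in dm6, with a summit outside annotated genes, within 500 bp of the TSS of Naus. The next, 8663, was at X:3719478-3720184, near the TSSs of Tlk, a protein kinase gene, and Rala, a small GTPase gene. The third, 8377, was at 3L:6184585-6185361, near the TSSs of D19B, which encodes a zinc finger protein, and CG43293. Both summits lay outside annotated genes, within 500 bp of those TSSs. These 3 peaks held ranks 1 to 3 in each replicate's own list, and the fourth, at CG42724 (3R:6367944-6369044, signal 6158), ranked 4 in all 3. The median signal of the optimal set was 199.3, and the signal is the authors' own value, used here only to rank peaks within a list.

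Of the 20 strongest peaks supported by all 3 replicates, 16 had a summit within 500 bp of a protein-coding TSS. After the leading 4 these were l(3)psg2; sti and tral, at a shared start (sti encodes citron kinase, which acts in cytokinesis, and tral an RNA-binding protein); Ptx1, a homeobox gene; CG10492; zf30C, a zinc finger gene; fwd, a phosphatidylinositol 4-kinase gene; CG14100; Ugalt, a UDP-galactose transporter gene; CG9784 and Nup153, the latter a nuclear pore gene; D19A, a neighbour of D19B; CG1910; and prtp. Of the other summits, 3 lay in introns. One was in Kr-h1 (2L:6088200-6088845), a zinc finger gene of the juvenile hormone response. The others were in ush (2L:480845-481333), which encodes a partner of GATA factors, and in CG11050 (2L:6612481-6612913). The last was intergenic, at X:123725-124309, 2696 bp from the nearest TSS, that of CG17636. None of these 20 peaks ranked below 47 in any replicate.

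The replicates shared most of their strong peaks. Between pairs of replicates, 80.3 to 81.9% of the 5202 strongest peaks of one were overlapped, by 1 bp or more, by the 5202 strongest of another, with a mean of 81.3% over the 6 comparisons. Rotating the peaks along their chromosome arms gave 2.93% on average (permutation tests, two-sided, p = 0.001 in each, the smallest that 1000 rotations can give). This comparison was added after the data were seen. The optimal peaks are the 5202 strongest regions of the pool of these same replicates, so their overlap with each replicate is not independent of it. Of the optimal peaks, 89.2%, 87.7% and 87.9% were overlapped by 1 of the 5202 strongest peaks of replicates 1, 2 and 3, a mean of 88.3% ± 0.785 (SD, n = 3). All 3 replicates supported 3808 optimal peaks (73.2%, 95% Wilson interval 72.0 to 74.4%), while 974 were supported by 2 replicates, 401 by 1 and 19 by none. Spearman's rho of peak signal over optimal peaks was 0.777 for replicates 1 and 2, 0.771 for 1 and 3, and 0.818 for 2 and 3, a mean of 0.788 ± 0.0254 (SD over 3 pairs). This correlation is across peaks that rank highest in the pool of the same replicates, and peaks are not independent replicates.

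Summits were concentrated at promoters and rare in coding exons. Within 500 bp of a protein-coding TSS lay 2932 of 5202 summits, or 56.4% (Wilson interval 55.0 to 57.7%), 4.92 times the 11.5% found after rotation (permutation test, two-sided, p = 0.001). The 5202 strongest peaks of the single replicates gave 56.1% ± 2.29 (SD, n = 3). Introns held 29.5% of summits against 39.9% after rotation, intergenic sequence 11.0% against 27.9%, coding exons 0.269% against 13.9%, and 3' UTRs 0.673% against 4.52% (permutation tests, each adjusted p = 0.0014). The shares in 5' UTRs outside promoters (0.557% against 0.787%, adjusted p = 0.115) and other exons (1.65% against 1.59%, adjusted p = 0.741) did not pass the permutation test. Among 14577 regions of the pooled relaxed list that lay below its median signal rank and overlapped no optimal peak, called weak regions here, 17.1% of summits were at promoters. Against these the 5' UTR share, 1.08% in weak regions, passed the test (Fisher's exact test, adjusted p = 0.000673).

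Stronger peaks lay at promoters more often than weaker ones. The promoter share was 65.9% (Wilson interval 63.3 to 68.4%) in the strongest 25% of optimal peaks and 49.9% (47.2 to 52.6%) in the weakest 25% (Fisher's exact test, two-sided, p = 1.7e-16), with 56.5% and 53.2% between them. The same difference taken in each replicate's strongest peaks was 17.5 percentage points ± 2.56 (SD, n = 3), positive in 3 of 3. At promoters, the median distance of the summit from the nearest TSS was -92 bp (bootstrap 95% interval -97 to -88 bp), with negative values upstream, and 82.5% of these summits were upstream. Medians in the replicates were -83, -102 and -88 bp, a mean of -91 bp ± 9.85 (SD, n = 3). A summit between the starts of head-to-head genes, neighbours read in opposite directions from close starts, is upstream of whichever is nearer. The distances and the upstream share were not split by such pairs.

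**Figure D2:**
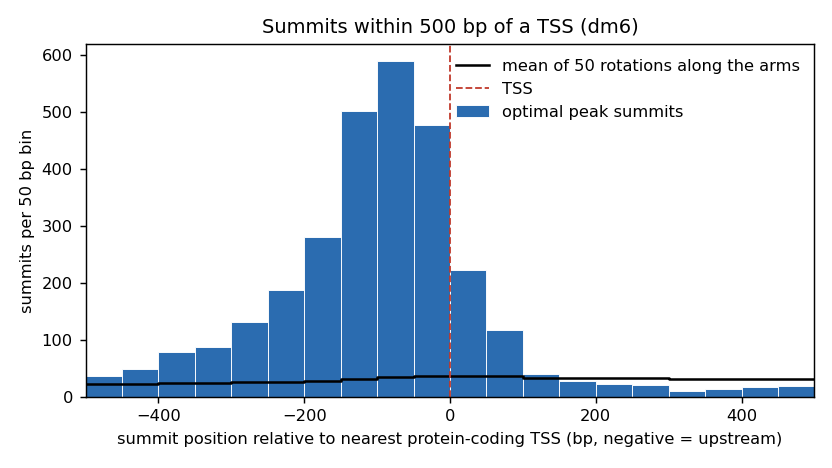
Optimal peak summits per 50 bp bin by distance in bp from the nearest protein-coding TSS, with negative values upstream, and the mean of 50 rotations as a black line. Of the 2932 summits shown, 82.5% lie upstream, with a median of -92 bp.

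Genes for ribosomal proteins carried promoter peaks more often than other genes. Of 13945 protein-coding genes, 3647 had a summit within 500 bp of a TSS (26.2%; 25.6% ± 0.736 in the replicates' strongest peaks, SD, n = 3), and these genes are called bound. Among 92 cytoplasmic ribosomal protein genes 65 were bound (70.7%, against 25.9% of other genes; Fisher's exact test, adjusted p = 5.0e-18), with 65.6% ± 7.40 in the replicates (SD, n = 3). Their strongest peaks were at RpS29 (3R:9777846-9778171, rank 159), RpL7 (rank 227), RpL34b (rank 268) and RpS27 (rank 358). Of 73 genes for mitochondrial ribosomal proteins, 41 were bound (56.2% against 26.0%; Fisher's exact test, adjusted p = 3.1e-07; 52.5% ± 0.791 in the replicates, SD, n = 3). Their strongest peaks were at mRpS10 (3R:15229328-15229744, rank 29), mRpL41 (rank 32), mRpS23 (rank 41) and mRpL23 (rank 75). Of these 8 peaks, those of RpS29 and mRpL41 had no other protein-coding start within 500 bp of the summit. The others also lay near Ripalpha (RpL7), CG8132 (RpL34b), Nup37 (RpS27), Art3 (mRpS10), CenG1A (mRpS23) and CG9004 (mRpL23).

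Genes for chromatin regulators and for the cell cycle were also bound more often. Cell cycle genes reached 20 of 30 (66.7%; Fisher's exact test, adjusted p = 1.7e-05), led by Dp, which encodes a partner of the E2F factors (rank 417), the replication helicase gene Mcm2 (rank 862), the cyclin gene CycE (rank 1168) and the mitotic kinase gene aurA (rank 1286). Of 19 Polycomb group genes 13 were bound (68.4%; Fisher's exact test, adjusted p = 0.0005), with the strongest peaks at ph-p (rank 40), Psc (rank 233), the histone methyltransferase gene E(z) (rank 446) and Sfmbt (rank 1004). Trithorax group and remodelling genes gave 13 of 22 (59.1%; Fisher's exact test, adjusted p = 0.00303): the Mediator gene skd (rank 106), the remodelling ATPase genes brm (rank 161) and Ino80 (rank 236), and Trl, which encodes GAGA factor (rank 480). Genes of insulator and architectural proteins gave 15 of 26 (57.7%; Fisher's exact test, adjusted p = 0.00303), with Chro (rank 31), Cp190 (rank 172), Trl, which both lists hold, and M1BP (rank 1173). Spliceosome and mRNA processing genes gave 12 of 24 (50%; Fisher's exact test, adjusted p = 0.0416), led by U2af50 (rank 573), CstF64 (rank 944), Cbp20 (rank 998) and Prp31 (rank 1612). The peaks of ph-p, Psc, skd, Trl, Dp and CycE had no other protein-coding start within 500 bp of the summit, while the others lay near at least 1 more. All 7 lists lay above the share of all genes in 3 of 3 replicates, and the peaks named for them were supported by all 3.

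Among these 7 lists, the call of the cytoplasmic ribosomal list alone held under every alternative run. With head-to-head genes left out, an alternative added after the data were seen, 4 lists did not pass on the fewer genes that remained, though their shares stayed above the 16.3% of other genes (Fisher's exact test): mitochondrial ribosomal (30%, adjusted p = 0.258), trithorax (37.5%, 0.258), insulator (40%, 0.0919) and spliceosome (33.3%, 0.389). With the strongest 50% of optimal peaks, the Polycomb (26.3%; Fisher's exact test, adjusted p = 0.484), insulator (30.8%, 0.156), cell cycle (30%, 0.142) and spliceosome (20.8%, 0.720) lists did not, against 15.4% of other genes. With only genes that had a relaxed pooled summit as background, the Polycomb (72.2%; Fisher's exact test, adjusted p = 0.139), trithorax (68.4%, 0.223), insulator (65.2%, 0.261) and spliceosome (60%, 0.493) lists did not pass against 48.2% of other genes, while homeotic and segmentation genes were bound less often (0.0297 for each). With peaks supported by all 3 replicates the Polycomb list was at 42.1% against 20.04% and the spliceosome list at 29.2% against 20.1% (Fisher's exact test, adjusted p = 0.0924 and 0.446). The spliceosome call was also lost with the fewer optimal peaks supported by both other replicates when replicate 1 (37.5% against 21.2%), 2 (33.3% against 21.8%) or 3 (37.5% against 21.6%) was left out (Fisher's exact test, adjusted p = 0.162, 0.332 and 0.143). The same held for windows of 200 bp (37.5% against 19.5%; Fisher's exact test, adjusted p = 0.0814) and 1000 bp (50% against 29.2%, 0.0731) and for any overlap of the peak (50% against 27.6%, 0.0508). Each of these shares stayed above that of other genes.

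Genes for chemosensory receptors and cuticle proteins were bound less often than other genes. Only 2 of 179 odorant, gustatory and ionotropic receptor genes were bound (1.12%; Fisher's exact test, adjusted p = 1.2e-19), namely Ir60e (rank 2774, supported by 3 replicates) and Gr63a (rank 4964, supported by 1). These peaks also lay near the starts of CG13585 and Lamtor4. None of 100 cuticle protein genes was bound (Fisher's exact test, adjusted p = 7.6e-13), which allows a share of up to 3% by the limit of 3 counts and of 3.70% by the Wilson interval. Both lists lay below the share of all genes in 3 of 3 replicates. Among only genes that had a relaxed pooled summit, the shares were 13.3% of receptor genes and 0% of cuticle genes, against 48.3% of other genes. The adjusted p-values there were 0.0297 and 0.0219 (Fisher's exact test). Gene activity was not taken into account. The other 13 lists did not pass the test (Fisher's exact test, adjusted p in parentheses below). By the exact test, bound were 16 of 48 genes for proteasome subunits (33.3%, adjusted p = 0.327), 18 of 44 for translation initiation factors (40.9%, 0.0822), 12 of 40 for respiratory complex I (30%, 0.621), 8 of 18 of the Notch pathway (44.4%, 0.175), 10 of 25 for heat shock proteins and chaperones (40%, 0.178), 6 of 18 ecdysone response genes (33.3%, 0.621) and 6 of 19 germ line and piRNA pathway genes (31.6%, 0.621). For patterning and tissue lists the values were 0 of 8 homeotic genes (0.178), which allows up to 37.5% by the limit of 3 counts and 32.4% by the Wilson interval, and 3 of 28 segmentation genes (10.7%, 0.160), 4 of 24 dorsoventral patterning genes (16.7%, 0.439), 2 of 22 neural progenitor and proneural genes (9.09%, 0.160), 2 of 19 differentiated neuron genes (10.5%, 0.259) and 4 of 20 muscle structural genes (20%, 0.621). Translation initiation factors passed with optimal peaks supported by both replicates other than 2, and with a promoter window of 200 bp (Fisher's exact test, adjusted p = 0.028 and 0.0282).

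**Figure D3:**
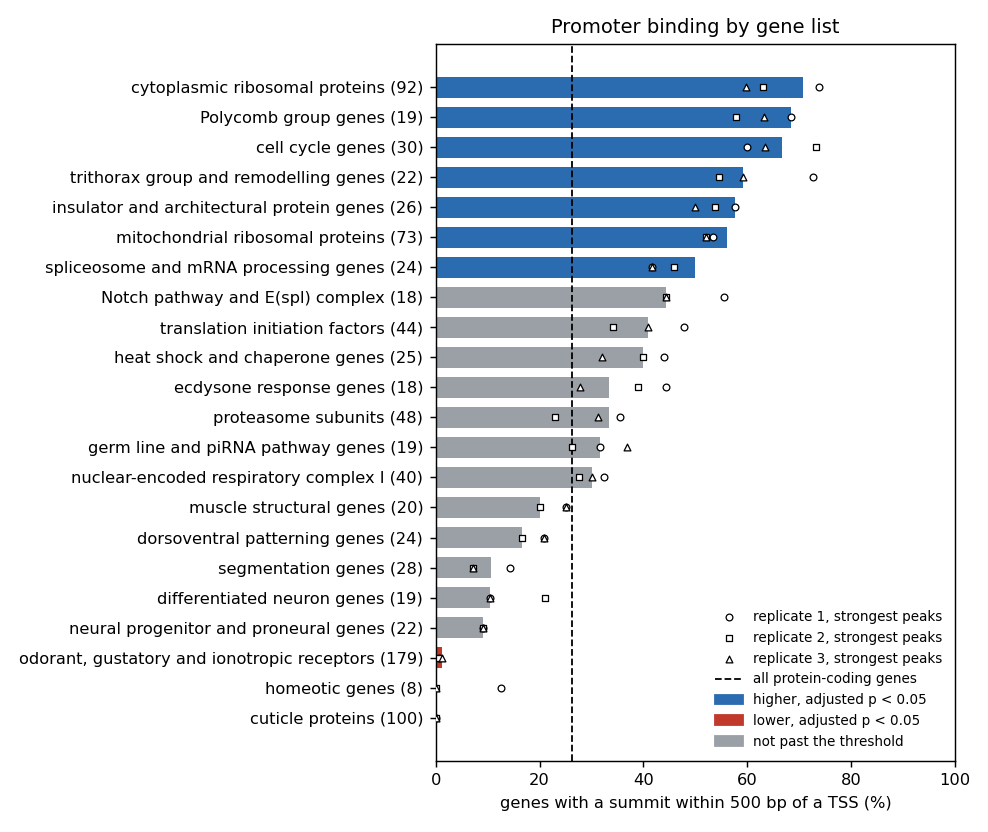
Percent of protein-coding genes in each fixed list with an optimal summit within 500 bp of a TSS (bars; list size in parentheses), with the same share in each replicate's 5202 strongest peaks (open symbols) and the 26.2% of all genes (dashed line). Cytoplasmic ribosomal protein genes reach 70.7% and cuticle protein genes 0%.

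Genes that face another gene head to head were bound more often than others. Of 3815 genes with the TSS of another protein-coding gene on the opposite strand within 500 bp upstream, 1990 were bound (52.2%, Wilson interval 50.6 to 53.7%), against 1657 of 10130 others (16.4%, 15.6 to 17.1%). The odds ratio was 5.58 (95% interval 5.13 to 6.06), with a Fisher's exact p too small for double precision. Both treat genes as independent, while 872 of 1736 head-to-head pairs of 2 genes had a summit counted for both. The interval is therefore too narrow, and promoters counted once are given further below. The difference was 34.8 percentage points ± 0.384 in the replicates (SD, n = 3). By chromosome, 10 of 80 genes on 4 were bound (12.5%, 6.93 to 21.5%) and 521 of 2196 on X (23.7%, 22.0 to 25.5%), against 26.7% (25.9 to 27.5%) on 2L, 2R, 3L and 3R together (Fisher's exact test, adjusted p = 0.00362 for each). In the replicates' strongest peaks, the difference from those arms was -12.7 points ± 6.59 for 4 and -2.13 points ± 0.343 for X (SD, n = 3). Taken singly, those arms differed among themselves, with 24.5% of genes bound on 2R, 26.2% on 2L, 26.3% on 3L and 29.3% on 3R. The interval for X held the share of 2R and lay below those of 2L, 3L and 3R, so X was not set apart from every arm. X and 4 were not tested against single arms, and no cause was tested. Peak density was 11.9 per Mb on 4 and 40.0 per Mb on X, and the other arms ranged from 36.7 on 2R to 42.3 on 2L.

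The DRE, Ohler motifs 1 and 7 and the CTCF core were more frequent at summits than beside them. The DNA replication-related element, DRE (TATCGATA), occurred within 50 bp of 2.86% of summits and in 0.384% of flanks of the same total width 500 bp away, a ratio of 7.45 (exact McNemar test, adjusted p = 1.6e-24; 6.74 ± 0.446 in the replicates, SD, n = 3). Ohler motif 1 (GGTCACAC), the sequence bound by M1BP, was found at 1.65% against 0.269%, a ratio of 6.14 (exact McNemar test, adjusted p = 3.6e-13), and Ohler motif 7 (CAKCNCTR) at 8.67%, a ratio of 2.55 (adjusted p = 7.9e-29). The CTCF core, recognised by an insulator protein, had a ratio of 5.29 (0.711% against 0.135%; exact McNemar test, adjusted p = 1.5e-05), and of 2.80 in the strongest 50% of peaks (adjusted p = 0.117). At summits over 500 bp from a TSS the ratios of DRE, motif 1 and motif 7 were 1.14, 2.33 and 1.03 and did not pass the exact test (adjusted p = 1, 0.540 and 1), while the call of the CTCF core, with a ratio of 5.50, held. With flanks 200 bp away the ratio was 3.04 for DRE and 1.51 for motif 1 (exact McNemar test, adjusted p = 1.4e-12 and 0.0297). In the strongest 50% of peaks these ratios were 4.83 and 3.89, and motif 1 was at 3.65 against weak regions. Within 100 bp of the summit the CTCF core had a ratio of 2.25. Against dinucleotide-shuffled copies of the summit windows, a control added after the data were seen, DRE, motif 1 and the CTCF core had ratios of 15.4, 15.8 and 16.1. Motif 7 had a lower ratio, 3.16.

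Higher ratios were also found for AT-rich sequences, and the summit windows held 35.6% GC against 44.2% in windows centred 500 bp to either side. The ratio was 1.93 for Ohler motif 6, 1.74 for the TATA box, 1.58 for the homeodomain core, 1.58 for the Su(Hw) core and 1.29 for the poly(A) tract (exact McNemar tests, largest adjusted p = 0.0157). Lower at summits were the CA repeat (ratio 0.321; exact McNemar test, adjusted p = 1.4e-20), the GAGA element (0.601, adjusted p = 6.1e-05), the E-boxes CAGCTG (0.816, adjusted p = 0.0318) and CACGTG (0.653, adjusted p = 0.0365), and the CRE (0.278, adjusted p = 0.0144). These 9 higher and 5 lower motifs, out of 22, had the same direction in 3 of 3 replicates. At summits over 500 bp from a TSS the CRE was found at 0 and its call held (exact McNemar test, adjusted p = 0.0123). Its call was lost within 100 bp of the summit (0.643; exact McNemar test, adjusted p = 0.213), with flanks 200 bp away (0.333, 0.0588), within 500 bp of a TSS (0.556, 0.502), in the strongest 50% of peaks (0.571, 0.724) and against weak regions (0.467; Fisher's exact test, adjusted p = 0.212). Near TSSs, at other summits, in the strongest 50% and against weak regions, CACGTG had ratios of 0.646, 0.667, 0.686 and 0.808 (exact tests, adjusted p = 0.135, 0.394, 0.313 and 0.340) and the Su(Hw) core of 1.64, 1.53, 1.68 and 1.23 (0.132, 0.155, 0.0739 and 0.191). CAGCTG did not pass near TSSs (0.939; exact McNemar test, adjusted p = 0.706), within 100 bp (0.927, 0.232) or in the strongest 50% (0.75, 0.0599), nor did the GAGA element near TSSs (0.841, 0.502), or Ohler motif 6 and the poly(A) tract at other summits (1.41, 0.0802, and 1.19, 0.155). Against the shuffled copies, the direction turned for the homeodomain core (ratio 0.870), CA repeat (3.56), GAGA element (2.92), CAGCTG (2.72) and CRE (1.25), and the Su(Hw) core did not pass (1.14; exact binomial test, adjusted p = 0.249). Against weak regions it turned for the poly(A) tract (0.736), GAGA element (1.07) and CAGCTG (1.05), and the TATA box had a ratio of 1.12, against 1.22 with shuffled copies. The 8 remaining motifs did not pass: the initiator (ratio 0.895), Zelda heptamer (0.686), E2F site (0.872), Pho core (0.743), bicoid-class site (0.956), orphan nuclear receptor sequence CAAGGTCA (0.75), Ets site (0.632) and B box of tRNA genes (1.33), with a smallest adjusted p of 0.116. Of these, the Zelda heptamer passed within 100 bp of the summit (0.549; exact McNemar test, adjusted p = 0.00238), and the initiator (0.874) and the Pho core (0.623) against weak regions (Fisher's exact test, adjusted p = 0.0172 and 0.00349). The bicoid-class site was higher with flanks 200 bp away (1.32; exact McNemar test, adjusted p = 0.0288) and lower against shuffled copies (0.707; exact binomial test, adjusted p = 1.9e-06), where the Ets site (2.35, at 12 summits) and the B box (8, at 4 summits) were higher (adjusted p = 0.0099 and 0.00296).

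Without a fixed list, 6-mers that share bases with the DRE had the largest ratios. Among 2080 6-mers merged with their reverse complements, 495 were higher and 959 lower at summits (exact McNemar test, adjusted over all 6-mers). The largest ratios among those at 100 or more summits were 3.20 for CGATAG (8.13% of summits; exact McNemar test, adjusted p = 1.7e-36) and 2.64 for TATCGA (10.4%, adjusted p = 5.3e-36), followed by CGCTAG (2.60), TACTAA (2.45) and ACTAGT (2.40). Ratios in the replicates were 3.06 ± 0.362 for CGATAG and 2.65 ± 0.224 for TATCGA (SD, n = 3). Summit windows held less GC than flanks, and 6-mers were not compared with shuffled copies or weak regions. Base composition was therefore not separated from these counts or ratios.

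**Figure D4:**
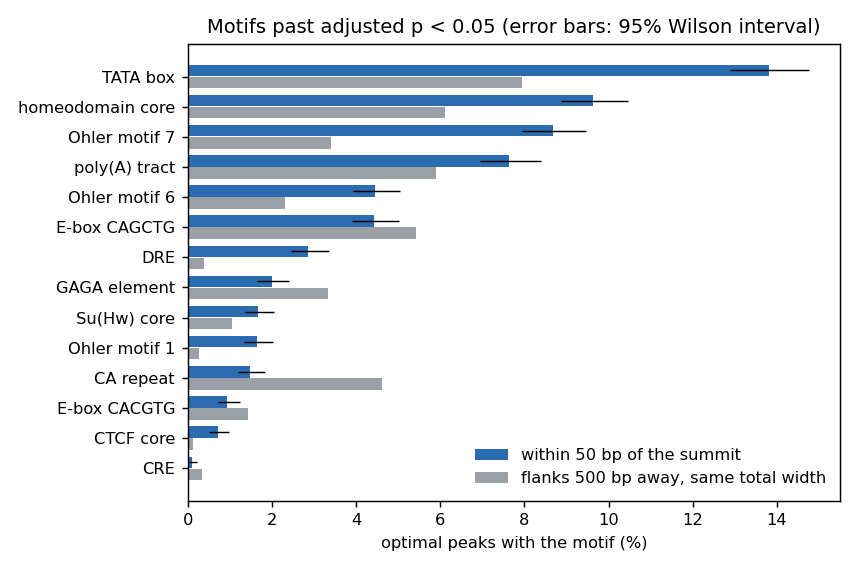
Percent of the 5202 optimal peaks with each of the 14 motifs past the test within 50 bp of the summit (blue, with 95% Wilson intervals) and in flanks of equal total width 500 bp away (grey). DRE is at 2.86% against 0.384% and the CA repeat at 1.48% against 4.61%.

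The lists on the older build dm3 described the same libraries. The optimal set held 5157 peaks on dm3, and the share per arm was close: 2L held 19.2% on dm3 and 19.1% on dm6, 2R 17.9% on both, 3L 20.2% and 20.3%, 3R 24.3% and 24.4%, 4 0.291% and 0.308%, and X 18.2% and 18.1%. No coordinates were converted between builds.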

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

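No test was run on these results, and both were looked up as data that the main comparisons do not use. The alternative background of genes with a relaxed pooled summit does draw on the whole dm6 pooled list. In the dm6 pooled relaxed list 594 regions had the highest −log10 q-value and overlapped no optimal peak. Since the optimal set holds the 5202 strongest pooled regions, regions outside it cannot have a signal above its lowest, 116.3. The median signal of these 594 regions was 110.6, and 40.9% of their summits lay within 500 bp of a TSS. On dm3, 78 pooled relaxed regions (0.260% of 30000) lay on sequences outside the 6 arms, among them 26 on 3LHet, 20 on 2RHet and 17 on 3RHet, the heterochromatic sequences of that build. The strongest of these ranked 6014, and none of the 5157 optimal dm3 peaks lay there.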

How the results depend on the processing

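Chosen after the data were seen were the shuffled copies, the lists without head-to-head genes, the overlap of the replicates' own peaks and the removal of close summits. Of 100 alternatives to the main comparisons, 87 kept the direction, the side of the threshold or the size. Promoter share, its rise with signal, head-to-head genes, X, 4 and the median distance to the TSS did so under every alternative run for them. Mean replicate support moved to 74.9% with a reciprocal overlap of 50%, to 99.8% with whole relaxed lists and to 81.3% with each replicate's own strongest peaks in place of the optimal set. Peaks in all 3 replicates numbered 2831 (54.4%) with the first of these and 5169 (99.4%) with the second, and 1918 (73.7%) with the strongest 50% of each list, which holds fewer peaks by construction. Over the 2 replicates that remain when 1 is left out, with the optimal set unchanged, support ranged from 87.8 to 88.5%. Peaks in both numbered 4126 to 4146, and rho of the remaining pair was 0.771 to 0.818. Support and rho here restate the values of single replicates and pairs. They do not test how far the set rests on 1 replicate, though they are counted among the 100 alternatives. Lists bound more often fell from 7 to 3 with the strongest 50% of peaks, with the background of genes that have a relaxed pooled summit, and without head-to-head genes, the last added after the data were seen. Each of these alternatives uses fewer peaks or genes, and the cause was not tested further. Lists bound less often rose from 2 to 4 with the relaxed background, where homeotic and segmentation genes joined. Motifs higher at summits fell from 9 to 3 away from TSSs, and motifs lower from 5 to 1 near TSSs and to 2 in the strongest 50%. Against shuffled copies 12 motifs were higher and 3 lower, and of these 3 only CACGTG (0.723) was among the 5 lower against flanks.

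Among lists, directions turned for some that had not passed: proteasome subunits at 10.4% (strongest 50%), 12.5% (support by all 3 replicates) and 12.5 and 20.8% without replicate 1 and 3, but not at 22.9% without replicate 2, germ line genes at 15.8% with support by all 3 and 21.1 and 15.8% without replicate 1 and 3, but not at 26.3% without replicate 2, complex I at 42.9% with the relaxed background and 10% without head-to-head genes, and there also dorsoventral genes at 17.4% and muscle genes at 16.7%. Other exons turned at 1.65% against weak regions and 1.58% in the strongest 50% of peaks. Motif ratios that turned were, against weak regions, 1.05 for CAGCTG, 1.07 for GAGA and 0.736 for poly(A), and against shuffled copies 2.72 for CAGCTG, 2.92 for GAGA, 1.25 for CRE, 0.870 for the homeodomain core and 3.56 for the CA repeat. Among motifs that had not passed, E2F turned at 1.01 within 100 bp, 1.12 against weak regions and 1.19 against shuffled copies, the bicoid-class site at 1.32 with flanks 200 bp away and 1.15 in the strongest 50%, the Pho core at 1.04 there, the Ets site at 3 with flanks 200 bp away, 1.5 in the strongest 50%, 1.401 against weak regions and 2.35 against shuffled copies, and the initiator at 1.05 against the last. Away from TSSs the ratio was 2 for CAAGGTCA, 1 for the Ets site and 0 for the B box. The cause was not tested. The dm3 rank at CG12155 was not run, because no dm3 annotation was used. Depth is unknown, so its effect on these values could not be weighed.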

Other observations

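The tests of single motifs with flank windows shuffled alike, of the homeodomain core alone, of DRE with motifs 1 and 7 alone, of the CTCF core alone, of AT-rich motifs at bound TSSs, of the CTCF core and TATA box away from TSSs and of head-to-head promoters counted once were chosen after the result was seen, and the C2H2 hypothesis came from the names at the strongest peaks.

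Genes for C2H2 zinc finger proteins, most of them DNA-binding regulators, carried promoter peaks more often than other genes. The 232 genes whose protein holds 3 or more matches to a C2H2 finger pattern were bound in 86 cases, or 37.1% (Wilson interval 31.1 to 43.4%), against 26.0% of 13713 others (Fisher's exact test, two-sided, p = 0.000277; 36.5% ± 2.63 in the replicates, SD, n = 3). The highest-ranked were D19B (rank 3), zf30C (rank 10), D19A (rank 16), CG1792 (rank 113) and MTF-1 (rank 127), the metal-responsive factor gene. An excess of head-to-head promoters does not account for this as a whole, since among genes that are not head to head 24.7% of C2H2 genes were bound against 16.2% of others (Fisher's exact test, p = 0.00799). That peaks may favour promoters of zinc finger genes stays a hypothesis, since it was found and tested on the same peaks, and no biological explanation was tested.

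None of 4 kinds of noncoding genes passed the test for summits at their starts. Among genes over 1000 bp from any protein-coding TSS, 8 of 211 tRNA genes, 6 of 184 snoRNA genes and 108 of 2331 other noncoding RNA genes had a summit within 500 bp, against 7.68, 6.715 and 87.4 after rotation (permutation tests, adjusted p = 1, 1 and 0.22). For snRNA genes it was 5 of 27 against 1.06, with a permutation p of 0.02 before and 0.08 after adjustment over the 4 kinds of gene.

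Head-to-head genes were bound at 52.2% against 16.4% of others. Counting 1 peak for both genes does not account for it: with each of 1843 head-to-head promoters counted once, 53.8% were bound, where independent promoters at the rate of single genes would give 30.8% (exact binomial test, p = 9.5e-93). Close spacing of genes does not account for it as a whole either, since 18.9% of 2686 genes lying head to tail within 500 bp of their upstream neighbour were bound. Their odds of being bound were 0.214 times those of head-to-head genes (95% interval 0.191 to 0.240). The share of head-to-tail genes was still above the 15.4% of 7444 genes in neither arrangement (Fisher's exact test, two-sided, p = 3.9e-05). No biological explanation was tested.

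DRE, Ohler motifs 1 and 7 and the CTCF core were higher at summits, and so were AT-rich sequences. Base composition does not account for the former. Their excess over shuffled copies was 5.99, 12.6, 3.36 and 8.30 times that of flank windows shuffled alike (lowest bootstrap bound 2.92). CAGCTG and the GAGA element, both lower at summits, reached 1.25 and 1.27 with lower bounds of 1.07 and 1.03, so a value just above 1 excludes little. Among motifs that had not passed, the E2F site reached 1.56 (1.23 to 1.91). The Ets site and the B box, found at few summits, reached 2.11 (0.895 to 4.31) and 4.22 (0.426 to 28.4). The median ratio of DRE, motifs 1 and 7 and the CTCF core to dinucleotide-shuffled windows was 15.6. Motif 7 had 3.16, under the 3.56 of the CA repeat, so that ratio does not set it apart. Base composition could account for the AT-rich sequences. Their median of 1.29 to shuffled windows excludes nothing, and the bound set for it was too low, since the motifs lower at summits had a median of 2.72. Relative to flanks shuffled alike the excess was 1.13 for Ohler motif 6 (bootstrap interval 0.939 to 1.35), 1.11 for the poly(A) tract (0.990 to 1.24), 0.779 for the TATA box and 0.697 for the homeodomain core, the last at 0.870 to shuffled windows. That promoters carry such motifs with or without a peak was tested at bound against unbound TSSs. For DRE, motifs 1 and 7 and the CTCF core, the test set beforehand gave a median ratio of 2.02. It could not tell, since CTCF did not pass. Medians were 2.03 without CTCF, and 1.30 for Ohler motif 6 and the homeodomain core. These groups were formed after the single results were seen, so their medians decide nothing. Taken singly, shares at bound and unbound TSSs were 17.7% and 7.45% for DRE, 13.8% and 6.77% for motif 1, and 40.6% and 20.3% for motif 7. They were 20.2% and 14.7% for Ohler motif 6, and 32.4% and 26.2% for the homeodomain core. These values argue against equal shares for these motifs (Fisher's exact tests, adjusted over all motifs tested there, largest adjusted p = 1.5e-11). Unbound TSSs were not matched for promoter type, gene activity or base composition, so a difference in these cannot be told apart from the peak. Equal shares stay open near a TSS for the TATA box and the poly(A) tract, at a median of 0.989 (Fisher's exact test, p = 0.839 and 0.636), and for the CTCF core, at 1.41 (p = 0.139). Over 500 bp from a TSS the CTCF core and the TATA box still had ratios to flanks of 5.50 and 1.66, and no biological explanation was tested.

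Of 284 spacings under 250 bp between neighbouring summits in the optimal set, 202 (71.1%) were 200 to 210 bp and 25 were under 200 bp. Among weak regions, 34.8% of 532 were 200 to 210 bp and 17 were under 200 bp. No test was run on these values, and no cause was examined, a minimum distance between summits in peak calling included.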
